A study of Homo sapiens with 18 samples.

How the data were processed

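SNAI2 (Slug), a zinc finger transcription factor of the Snail family that binds E-box motifs, was mapped in human keratinocytes by chromatin immunoprecipitation and sequencing with a rabbit monoclonal antibody. The series holds 18 samples, of which 12 are SNAI2 ChIP libraries in 6 groups of 2 and 6 are input libraries, 1 per condition. The groups are control shRNA and SNAI2 shRNA in growth medium, and LACZ or SNAI2 overexpression, each in growth medium and in differentiation medium. Differentiation meant 3 days at confluence in 1.2 mM calcium, per the labels' protocols. Groups were taken from the source name of each sample. For 2 inputs the source name gives growth medium and another label gives differentiation medium. No input was analysed directly here, but the lists were called against input, so inputs bear on every region.

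The data analysed are 6 lists of significant regions, one per ChIP group, made with Partek on the hg19 build, per the submitters' processing notes. Each deposited region has a chromosome, a start, an end, a cytoband, a width in bp and the names of the libraries in which it was significant. Every region in these lists names both libraries of its group, so a list holds only regions shared by the pair, and a width equals the end minus the start. Other quantities per region, such as a p-value, an enrichment, a read count or a gene name, were not used here. The peak calling threshold, the input set against each group, the aligner and the reads per library are not given in the sources used here. The depth behind each list is therefore unknown, and lists can differ in length through depth or antibody recovery as well as through occupancy. Nothing in the labels says whether the libraries of a pair came from separate cultures.

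Coordinates are printed as deposited, on hg19. No hg19 sequence or annotation was used, so regions are placed by position and cytoband and are not assigned to genes, exons or introns. Where a cytoband is described by a gene it is known to hold, the region lies in the same band and not necessarily at the gene. Regions on chromosome Y were left out of every value, and band and chromosome tests used the 22 autosomes. Regions were put in 3 classes, namely contigs outside the assembled chromosomes, regions within 2 Mb of the gap between the last region of the short arm and the first of the long arm, and all others, called arm regions. The gap was set only where both arms held regions, so on chromosomes 13, 14, 15 and 22 every region counted as an arm region. Arm regions can therefore include sequence next to those centromeres, and sequence at chromosome ends.

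Regions of a pair of lists were called shared when they overlapped by at least 1 bp. Each of 6 pairs was compared with 1000 shuffles of the other list within its chromosomes (bedtools 2.31.1, two-sided, smallest possible p 0.002). Shares carry 95% Wilson intervals, which cover counting of regions only. Differences between shares were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 12 tests, and p-values under 1e-300 were written as 1e-300. Regions common to both growth lists were compared with the exact McNemar test. Median widths of shared and unshared regions were compared by a two-sided permutation test with 100000 resamples, for which 1e-05 is the smallest p. The unit of these tests is the region, with 1 list per group, so each p covers the lists compared and carries no spread between cultures.

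Each cytoband with 20 or more regions was tested for a differing share against all other bands (Fisher's exact test, two-sided, adjusted over the bands of that comparison). A set of 26 bands in 5 groups, chosen after the data were examined for textbook epidermal, basal, junction and other gene clusters, was tested the same way. Region density per autosome was correlated with protein-coding gene density by permutation (100000 resamples, 12 relations in the family). Gene numbers per chromosome came from an NCBI RefSeq gene table of GRCh38.p14, of which no coordinate was used, and chromosome lengths were taken as the last position of any region in the lists. On simulated lists built from the LACZ lists, planted shares of 5% and 15% of 7810 regions were recovered as 5.15% and 15.3%. In simulated band tests over 98 bands with 10 bands kept 3 times as often, 88% of planted bands were found on average over 20 runs, with 0.25 false calls per run. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

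The design fixed before the data were examined also planned tests of 10 gene lists, distance to transcription starts, E-box content, peak strength and reads per library. These need gene names, p-values, enrichment, reads or hg19 sequence and were not run. Region width took the place of peak strength, and cytobands took the place of gene lists. For the same reason the planned rule for naming regions by smallest p was replaced, after the data were examined, by the 5 widest autosomal arm regions of each set (and the 5 widest of the other classes for SNAI2 shRNA). Bands named outside the set of 26 are those past the threshold, or are stated to be chosen after their values were seen. Alternatives were a 1 kb window, overlap of 50% of the shorter region, other shuffles, lists without regions found in all 6, without unplaced sequence, without regions near centromeres, without regions under 150 bp, and lists cut to equal length by width.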

Results

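SNAI2 occupancy was mapped in keratinocytes, the main cell type of the epidermis, with SNAI2 lowered by shRNA or raised by overexpression, and before and after differentiation. LACZ, a bacterial gene, served as the overexpression control. Each of the 6 conditions had 2 ChIP libraries, and the regions significant in both libraries form its list. The lists held 5855 regions with control shRNA, 268 with SNAI2 shRNA, 7810 with LACZ in growth medium, 11891 with SNAI2 overexpression in growth medium, 1550 with LACZ after differentiation and 10280 with SNAI2 overexpression after differentiation. Regions were short, with median widths from 254 bp (control shRNA and differentiated LACZ cells) to 302 bp (differentiated SNAI2-overexpressing cells). There is 1 list per condition, so no list length has a replicate error, and the reads behind each list are unknown.

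**Figure D1:**
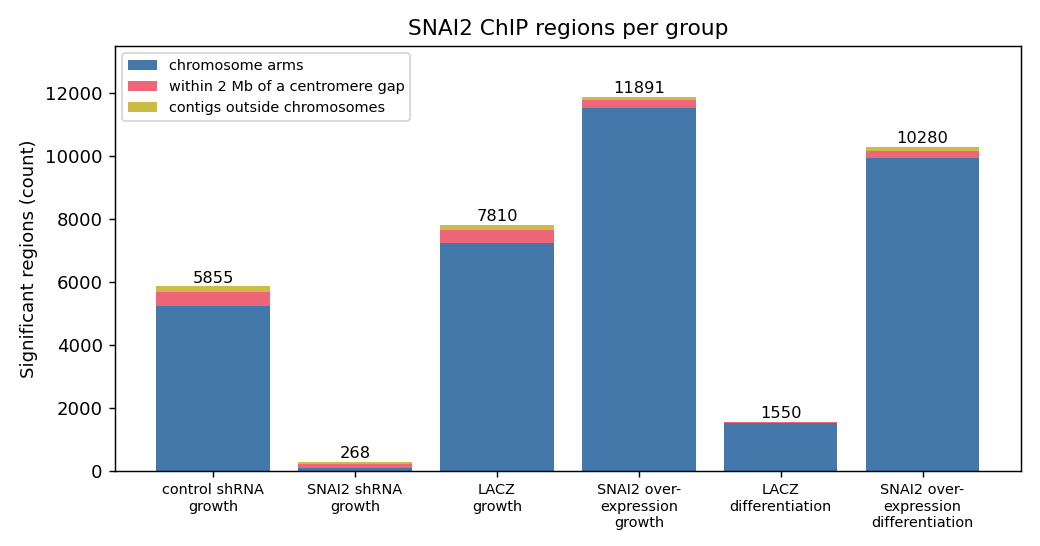
Number of significant SNAI2 ChIP regions (vertical axis, count) in each of the 6 groups (horizontal axis), with each bar divided into chromosome arms, sequence within 2 Mb of a centromere gap and contigs outside the chromosomes. The bars run from 268 regions with SNAI2 shRNA to 11891 with SNAI2 overexpression in growth medium.

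With SNAI2 shRNA, few of the SNAI2 regions were mapped again. The list shrank 21.8-fold, from 5855 regions to 268, and 198 control regions (3.38%, interval 2.95 to 3.88) were found again with SNAI2 shRNA. Of the 1550 widest control regions, 191 (12.3%) were. Among the regions absent after knockdown were wide ones at 20q13.33 (chromosome 20, 62446474 to 62447687), 9q22.31 (chromosome 9, 96434383 to 96435300), 17q25.3 (chromosome 17, 81008557 to 81009433) and 9q33.3 (chromosome 9, 129677194 to 129677897). Another lay at 8q11.21 (chromosome 8, 49434711 to 49435432, 721 bp), the band that holds the SNAI2 gene itself, and it was present in the 5 lists other than the knockdown. Bands with genes of epidermal differentiation held few or no regions. In the 4 bands of epidermal clusters, 2 of 84 control regions (2.38%) were found again, against 3.09% in other bands (Fisher's exact test, adjusted p = 1). Counts went from 29 to 1 at 1q21.3, the epidermal differentiation complex of cornified envelope genes such as FLG, LOR and IVL, from 21 to 1 at 12q13.13, the type II keratin cluster, and from 23 to 0 at 17q21.2, the type I keratin cluster. At 16q22.1, which holds the E-cadherin gene CDH1, they went from 23 to 0.

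The regions that stayed in the list with SNAI2 shRNA had an unusual distribution. Of the 268, 261 (97.4%) were also in the control list and 0 were private to the knockdown. Sequence flanking centromeres or on contigs made up 177 of them (66.0%, interval 60.2 to 71.5), against 620 of 5855 control regions (10.6%, Fisher's exact test, adjusted p = 3.12e-96). The bands 10q11.21, 16q11.2, 2p11.1 and 8p11.1, all next to centromeres, were the 4 of 59 tested in which control regions were found again more often than elsewhere. At 10q11.21 that was 24 of 44 regions (54.5%) against 2.67% in other bands (Fisher's exact test, adjusted p = 6.21e-24). Of control regions flanking centromeres or on contigs, 109 of 620 (17.6%) overlapped a knockdown region by at least 1 bp. This share rests on the 1 bp rule. Within 1 kb, 34 of 44 control regions at 10q11.21, 20 of 26 at 16q11.2, 15 of 25 at 8p11.1 and 16 of 38 at 2p11.1 were found again. At 16q11.2 the lists held 26 control and 27 knockdown regions. The contig gl000199 of chromosome 9 went from 154 to 20. On chromosome arms, 89 of 5235 control regions (1.70%) were found again, and the knockdown list held 91 arm regions. Named examples are regions at 17q25.3 (chromosome 17, 80745323 to 80745912), 8q24.3 (chromosome 8, 143808889 to 143809469) and 14q11.2 (chromosome 14, 20811575 to 20811896 in the knockdown list), each present in all 6 lists. The widest, at 5p15.33 (chromosome 5, 10027 to 11875), lies at the start of the chromosome's sequence. Control regions found again were wider, with a median of 529 bp against 250 bp for the rest (permutation test, p = 1e-05, the smallest possible), and on arms the medians were 420 and 248 bp.

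The control shRNA and LACZ lists, both from growth medium without a change to SNAI2, shared most of their regions. Of the control regions, 4859 (83.0%, interval 82.0 to 83.9) were in the LACZ list, and 4831 of 7810 LACZ regions (61.9%) were in the control list. Shuffled placement gave 79.5 ± 6.71 shared control regions (SD, 1000 shuffles, permutation p = 0.002, the smallest possible). On chromosome arms, 4499 of 5235 control regions (85.9%) were found with LACZ. The 5 of 59 bands in which control regions were found less often in the LACZ list were 16q11.2, 2p11.2, 4p11, 2p11.1 and 10q11.21, and at 16q11.2 it was 3 of 26 (11.5% against 84.4%, Fisher's exact test, adjusted p = 3.51e-14). No band was called with sequence flanking centromeres left out, which left each of these 5 under the minimum of 20 regions. With regions within 1 kb counted as shared, 10q11.21 lost its call. A slightly larger share of control regions (3.38%) than of LACZ regions (2.27%) was found in the knockdown list (Fisher's exact test, adjusted p = 8.75e-05), a difference of 1.12 points. It was 0.513 points on arms alone, and was not past the threshold when each list was reduced to at most its widest 1550 regions (1.29 points). Both shares are limited by the short knockdown list, more so for the longer LACZ list. Most control regions also lie in the LACZ list, so the regions tested are not independent. The difference is therefore bound to the list lengths, and is not evidence of a differing loss apart from them.

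**Figure D2:**
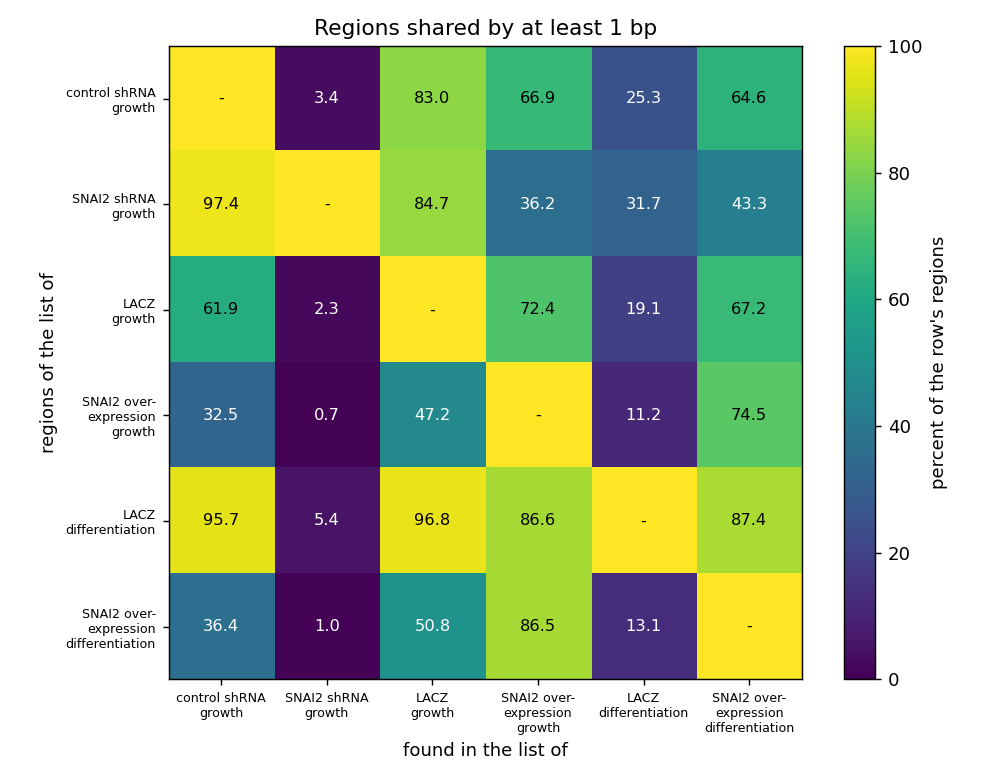
Percent of the regions of each list (rows) that overlap by at least 1 bp a region of each other list (columns), by colour and number. The list with LACZ after differentiation lies mostly within the LACZ growth list (96.8%), and 3.4% of control shRNA regions were found with SNAI2 shRNA.

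Fewer SNAI2 regions were mapped in LACZ control cells after differentiation. The list was 5.04-fold shorter (1550 against 7810 regions), and 1494 growth regions (19.1%, interval 18.3 to 20.02) were kept. Of the 1550 widest growth regions, as many as the differentiated list holds, 836 (53.9%) were kept. The differentiated list lay mostly within the growth list, since 1500 of its 1550 regions (96.8%) were there and 1484 (95.7%) were in the control shRNA list, with 19 in no other list. Kept regions included those at 2q37.3 (chromosome 2, 242144488 to 242146764, 2276 bp), 20q13.33 (chromosome 20, 62446508 to 62447714), 1p34.3 (chromosome 1, 39956667 to 39957659), 9p22.3 (chromosome 9, 14692853 to 14693837) and 17q25.3 (chromosome 17, 81008498 to 81009464). Lost ones included regions at 3q29 (chromosome 3, 196759919 to 196761892), 16q24.2 (chromosome 16, 87888534 to 87889483), 4q13.2 (chromosome 4, 68265135 to 68266816), 18p11.32 (chromosome 18, 107786 to 109088) and the 5p15.33 region at the chromosome's start.

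Width separated kept from lost regions. The median was 399 bp for kept and 268 bp for lost LACZ growth regions (permutation test, p = 1e-05, the smallest possible). Of arm regions, 29 of 1448 in the narrowest 20% (2.00%) and 888 of 1449 in the widest 20% (61.3%) were kept. Regions flanking centromeres or on contigs, though present in number with LACZ in growth medium (566), were kept in 22 cases (3.89%) against 20.3% of arm regions (Fisher's exact test, adjusted p = 2.74e-28), and at 10q11.21 counts went from 32 to 0.

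In bands of epidermal genes, the loss was broad. Counts from growth to differentiation went from 38 to 15 at 1q21.3, from 28 to 9 at 12q13.13, from 36 to 8 at 17q21.2 and from 13 to 2 at 18q12.1, the desmosomal cadherin cluster. They went from 73 to 22 at 17q25.3, which holds the differentiation regulator ZNF750, and from 36 to 9 at 16q22.1. At 1q21.3, 15 of 38 growth regions were kept (39.5%, interval 25.6 to 55.3) against 19.6% elsewhere (Fisher's exact test), with adjusted p = 0.175 over all bands and 0.0766 over the 26 chosen bands. The bands 8q11.21 (7 of 13) and 5q31.3, the protocadherin cluster (9 of 20), had the same adjusted p of 0.0766 over the chosen bands. The 4 bands of epidermal clusters together kept 33 of 115 regions (28.7% against 19.5%, Fisher's exact test, unadjusted p = 0.0178, adjusted 0.119). None of 98 bands passed the threshold by Fisher's exact test, and 10 had an unadjusted p under 0.05. With regions within 1 kb counted as shared, 4p16.3 (19 of 39, 48.7%) and 10q11.21 (0 of 32) passed it.

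**Figure D3:**
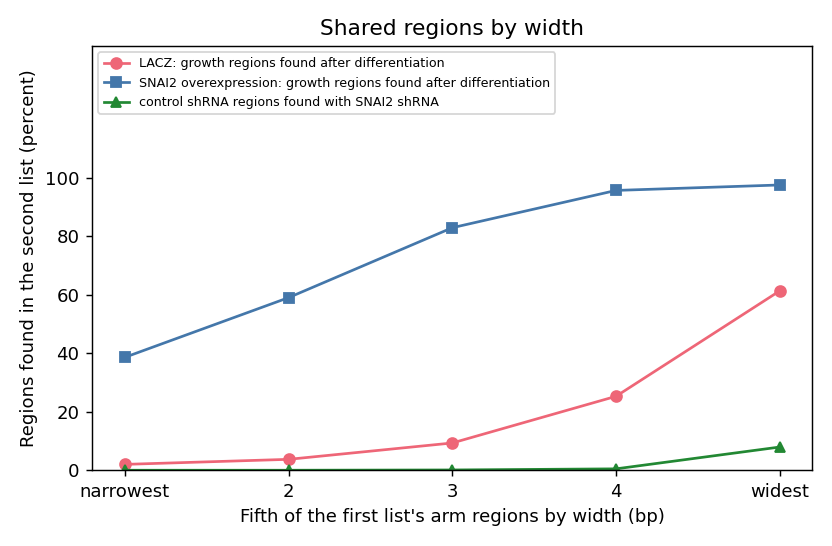
Percent of regions of one list found in another (vertical axis) against the width class of the arm regions of the first list (horizontal axis, 5 equal classes from narrowest to widest in bp). LACZ growth regions kept after differentiation rise from 2.00% to 61.3%, SNAI2 overexpression regions from 38.6% to 97.5%, and control regions found with SNAI2 shRNA from 0 to 7.93%.

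With SNAI2 overexpressed, most regions were still occupied after differentiation. Of 11891 growth regions, 8861 (74.5%, interval 73.7 to 75.3) were found in differentiated cells, and the list was 1.16-fold shorter. The LACZ share minus the SNAI2 share was -55.4 percentage points (Fisher's exact test, p at or under 1e-300, the smallest written), and -20.5 points when each list was reduced to its widest 1550 regions. The full-list shares are limited by list length. The differentiated list held 0.198 times as many regions as the growth list with LACZ, and 0.865 times with SNAI2. The reduced lists are not free of this limit, since the differentiated LACZ list of 1550 entered whole and the differentiated SNAI2 list was cut. Of the 5655 LACZ growth regions present in both growth lists, 1331 (23.5%) were kept with LACZ and 4964 (87.8%) with SNAI2. Among these, 3679 were kept with SNAI2 alone and 46 with LACZ alone (exact McNemar test, p at or under 1e-300). The McNemar test carries the same limit of list length. Growth regions kept numbered 46 of 58 at 1q21.3, 38 of 48 at 12q13.13, 57 of 74 at 17q21.2 and 51 of 65 at 16q22.1. The 4 bands of epidermal clusters together kept 78.2%, against 74.4% in other bands (Fisher's exact test, adjusted p = 0.707). The single bands with a lower share kept were 1q23.3 (20 of 43, 46.5%, Fisher's exact test, adjusted p = 0.0166) and 2p25.3 (11 of 27, 40.7%, adjusted p = 0.0166), 2 of 163 tested. Neither was called with regions within 1 kb counted as shared. The widest lost region lay at 1q23.3 (chromosome 1, 161431339 to 161433335).

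Within differentiated cells, SNAI2 overexpression gave 6.63 times as many regions as LACZ. Most LACZ regions were included, 1355 of 1550 (87.4%, interval 85.7 to 89.0), while 8932 of the 10280 SNAI2 regions (86.9%) were absent from the LACZ list. Against the 1550 widest SNAI2 regions alone, 576 LACZ regions (37.2%) were shared. Of the 6316 LACZ growth regions lost on differentiation, 3915 (62.0%) were occupied in differentiated SNAI2-overexpressing cells, among them those at 3q29 and 16q24.2 and others at 17q21.31 (chromosome 17, 41381605 to 41382395) and 10q22.2 (chromosome 10, 75909901 to 75910660). Of the 1494 kept ones, 1333 (89.2%) were (Fisher's exact test for the difference, adjusted p = 3.95e-104). This contrast was not matched on width, and kept regions were wider than lost ones (medians of 399 and 268 bp). None of 141 bands differed in the share of SNAI2 regions that LACZ cells also held (Fisher's exact test, 6 at an unadjusted p under 0.05). The wide regions absent from differentiated LACZ cells included 5p15.33 (chromosome 5, 897182 to 900205, 3023 bp) and 9q22.31 (chromosome 9, 96433173 to 96435381).

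In growth medium, SNAI2 overexpression added regions and left out some. The list was 1.52-fold longer than with LACZ, 5655 of 7810 LACZ regions (72.4%, interval 71.4 to 73.4) were retained, and 6276 SNAI2 regions had no LACZ counterpart. With both lists reduced to their widest 1550 regions, 726 LACZ regions (46.8%) were retained. Of all SNAI2 growth regions, 3778 (31.8%) were found in both overexpression lists and in none of the other 4. The widest of these lay at 18q23 (chromosome 18, 74104344 to 74106965, 2621 bp), 11q23.3 (chromosome 11, 119954214 to 119956524 and 119951807 to 119953301), 13q34 (chromosome 13, 114247005 to 114248986) and 19p13.2 (chromosome 19, 11320001 to 11321761). Counts went from 36 to 74 at 17q21.2, from 73 to 144 at 17q25.3, from 46 to 105 at 11q13.1, which holds OVOL1, and from 65 to 115 at 8q24.3, which holds the plectin gene PLEC. They went from 29 to 36 at 2q31.1, which holds ITGA6, from 20 to 26 at 5q31.3 and from 5 to 5 at 9q31.2, which holds KLF4. The desmosomal cadherin band 18q12.1 went from 13 to 8. None of 163 bands differed in the share of SNAI2 regions also found with LACZ (Fisher's exact test, smallest adjusted p = 0.503, 13 at an unadjusted p under 0.05), and with a 1 kb window 13q34 (lower) and 1q23.3 (higher) did. SNAI2 regions without a LACZ counterpart were less often found in differentiated SNAI2 cells than those with one (62.7% against 87.7%, Fisher's exact test, adjusted p = 4.06e-224). This contrast was not matched on width, with which both shares rose. From the narrowest to the widest 20% of SNAI2 arm regions, 22.3% to 78.9% were found with LACZ. In differentiated SNAI2 cells it was 38.6% to 97.5%.

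How often LACZ regions were retained under overexpression differed between bands. Among 98 bands, 12 had a higher share than other bands, including 19p13.3 (87 of 94, 92.6%, Fisher's exact test, adjusted p = 9.65e-05), 16p13.3 (84 of 93), 8q24.3 (60 of 65), 11q13.1 (43 of 46) and 17q25.3 (65 of 73). The 5 with a lower share were 20q11.22 (9 of 20) and, next to centromeres, 10q11.21 (3 of 32, 9.38%, Fisher's exact test, adjusted p = 2.59e-12), 1p11.2, 8p11.1 and 2p11.1. When bands with 10 or more regions were tested, 20q11.22, 11p15.5, 19p13.11, 1p36.33 and 5q35.3 lost their call. With a 1 kb window 8p11.1, 11p15.5, 19p13.11, 1p36.33 and 5q35.3 did. The lower minimum newly called bands with a lower share, 11p11.12 (0 of 17), 17p11.1 (0 of 11), 18q11.1 (0 of 11), 4p11 (4 of 17), 8q11.1 (6 of 16) and 8q22.1 (3 of 11). The 1 kb window newly called 19q13.33 (28 of 29), with a higher share. With regions flanking centromeres left out, 9 bands were called in place of 17, and 17q25.3 was not among the 9. Of the 9, 16p11.2 was newly called. In total, 186 of 566 regions flanking centromeres or on contigs (32.9%) were retained against 75.5% of arm regions (Fisher's exact test, adjusted p = 2.12e-92). Bands of single differentiation genes retained 213 of 249 LACZ regions (85.5% against 73.3%, Fisher's exact test, adjusted p = 1.37e-04) and passed the threshold without any one of the 7 bands. Most of these regions lay in 17q25.3 (65 of 73), 9q34.3 (53 of 62) and 11q13.1 (43 of 46). The other bands retained 10 of 10 at 14q12, 30 of 38 at 1p36.11, 10 of 15 at 6q21 and 2 of 5 at 9q31.2. The higher share is that of whole bands, mainly the larger ones, and was not traced to the genes. These bands were chosen after the data were examined, and 17q25.3 and 11q13.1 were also called singly, so the p is descriptive. Bands outside the chosen set, such as 19p13.3 and 16p13.3, had a higher share as well. Bands of basal and progenitor genes retained 138 of 166 (83.1% against 73.5%, Fisher's exact test, adjusted p = 0.0428), but 77.2% without 8q24.3 (adjusted p = 0.854). Without 17q25.1, 10q25.1 or 3q28 the share stayed at 83.7%, 83.1% and 83.0%, with adjusted p = 0.0847, 0.0623 and 0.0617 by Fisher's exact test. On arms alone it was 83.1% against 75.5% in other bands (adjusted p = 0.147 by Fisher's exact test). The other 3 groups of bands did not pass the threshold, with 78.3% retained in epidermal clusters (Fisher's exact test, adjusted p = 0.707), 77.8% in junction and mesenchymal transition bands (0.854) and 70.0% in clusters of other lineages (0.926).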

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

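Tests of the regions flanking centromeres, of list lengths on arms, and of the widest overexpression regions were chosen after the result was seen, as were the width comparison of kept and lost arm regions and the split of overexpression regions by width. The width bounds for knockdown regions on arms were set before.

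The share of growth regions kept on differentiation differed between LACZ and SNAI2-overexpressing cells, which is what marked it for a closer look. The LACZ share minus the SNAI2 share was -55.4 percentage points, -53.1 at equal width over 5 width classes and -20.5 in lists reduced to their widest regions. Equal width matched the growth regions only, and each was still sought in the full differentiated list. The values -55.4 and -53.1 are therefore bound to the list lengths, and are not evidence of a differing response apart from them. The value -20.5 is not free of this limit. The differentiated LACZ list, of 1550 regions, entered it whole, while the differentiated SNAI2 list was cut from 10280 to its widest. A difference in sensitivity could therefore still enter it. The short LACZ list could not come from loss of regions flanking centromeres or on contigs alone, as these were 566 of 7810 growth regions. Arm regions alone were 4.74 times as many in growth medium. Lower sensitivity of the differentiated LACZ libraries at unchanged sites stays open for the class next to centromeres or on contigs: its odds of being kept at equal width were 0.0765 times those of arm regions (Mantel-Haenszel, interval 0.0501 to 0.117), but 0.111 times in the longer SNAI2 growth list too. On arms, kept regions were wider by 136 bp in the median, as both lower sensitivity and less SNAI2 in differentiated cells could give. Width alone told kept from lost with an area under the ROC curve of 0.863, short of the 0.95 asked of lower sensitivity as the whole account, and without reads per library the explanations cannot be told apart.

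The regions left with SNAI2 shRNA are a mixture. For those flanking centromeres or on contigs, 66.0% of the list against 10.6% with control shRNA, a candidate explanation is reads from high-copy sequence that the assembly holds in few copies, which asks nothing of SNAI2. By an overlap of 1 bp, 109 of 620 control regions of this class (17.6%) were found again after knockdown. Within 1 kb it was 34 of 44 at 10q11.21, 20 of 26 at 16q11.2, 15 of 25 at 8p11.1 and 16 of 38 at 2p11.1. The cause of the absence of the others was not tested. For arm regions, SNAI2 left at the strongest sites may contribute, as their median width lay at percentile 96.5 of LACZ growth arm regions (86 regions). Enrichment that does not depend on SNAI2 also stays open: with overexpression their width was 0.869 times that with LACZ (median of 80, bootstrap interval 0.849 to 0.885). For 169 other regions of like width the ratio was 0.964, so part of this belongs to wide regions in general.

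The regions added by overexpression in growth medium could come from higher sensitivity of those libraries at unchanged sites or from binding at added sites. Among the widest 20% of LACZ growth arm regions, 3.93% were absent from the overexpression list, but among the narrower ones 29.6% (1718 of 5795) were. Higher sensitivity at unchanged sites does not by itself give such absences, but they also arose without a change to SNAI2. Of control arm regions, 4499 of 5235 (85.9%) were found in the longer LACZ list. The 29.6% therefore does not decide. For narrower overexpression regions the explanations cannot be told apart, as width near the detection limit and added binding are mixed there. For the widest 20% of overexpression regions on arms, 487 of 2307 (21.1%) were absent with LACZ. That was 7.28 times the share of the widest LACZ regions absent with control shRNA (42 of 1449, 2.90%). The comparison cannot decide, as the pairs of lists differ in length ratio (1.52 and 1.33) and may differ in sensitivity. Widths also differ between the growth lists. For arm regions in both, outside those with SNAI2 shRNA, the median ratio of overexpression to LACZ width was 1.11. It was 0.964 among 430 of these that were wide with LACZ. Binding at added sites when SNAI2 is abundant remains a hypothesis for the widest overexpression regions, as no reads or SNAI2 level was used here.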

How the results depend on the processing

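The overlap of each of the 6 pairs stayed above shuffled placement in all 54 alternatives, from those set before the data were examined (1 kb window, 50% overlap, chromosomes 1 to 22 and X, whole-genome shuffles, regions in all 6 lists left out) to those chosen after seeing the data (shuffles within cytobands, regions flanking centromeres or on contigs left out, regions under 150 bp left out, equal length by width). With lists reduced to at most their widest 1550 regions the shares moved: 12.3% of the widest control regions were found in the SNAI2 shRNA list of 268, 53.9% of LACZ growth regions after differentiation, 46.8% of them with SNAI2 overexpression, and 37.2% of differentiated LACZ regions in differentiated SNAI2 cells. The alternatives below were chosen after seeing the data, except list lengths on chromosomes 1 to 22 and X. Differences of overlap shares kept direction and side of the threshold in 30 of 31 alternatives. The exception is the share of control against LACZ growth regions found with SNAI2 shRNA, 1.29 points with each list reduced to its widest regions, which leaves fewer regions to test; on arms alone it fell to 0.513 points from 1.12. Without regions flanking centromeres or on contigs, the SNAI2 shRNA list fell to 91 regions, and the other 17 list lengths stayed within 1.5 times. That setting left 0 called bands for control regions with SNAI2 shRNA and 0 for control regions with LACZ, since each band called before fell under 20 regions and was not tested. For LACZ growth regions in the SNAI2 growth list 9 were called. Of these, 16p11.2 (31 of 32, Fisher's exact test, adjusted p = 0.0414) was newly called, with adjusted p = 0.0942 before. The cause of the change was not tested. With a 1 kb window, 2 bands were called for LACZ growth regions kept on differentiation, 2 for SNAI2 growth regions with LACZ and 0 for SNAI2 growth regions kept on differentiation, again with no test of the cause. Another 15 band counts stayed within 1.5 times, and 6 width differences kept their direction. Groups of gene bands kept their side of the threshold in 26 of 31 alternatives, all 5 others being for basal and progenitor bands. The share of regions flanking centromeres or on contigs moved with a 1 or 5 Mb limit in 10 of 12 cases. With LACZ after differentiation it went from 1.42% to 0.839% at 1 Mb and 4.71% at 5 Mb. In the SNAI2 shRNA list it was 66.0% at 1 Mb and 67.9% at 5 Mb. The kept shares of this class are given for the 2 Mb limit only.

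No paired analysis was possible because the lists hold only regions significant in both libraries of a group and no values per library, and leaving out a replicate could not be run for the same reason. Alternatives set before the data were examined that need p-values, enrichment, reads, gene windows or sequence were not run, among them stricter p thresholds, lists cut by p, gene body and 50 kb windows, start distances, E-box variants and other normalizations. Depth limits every list length here, since the reads per library are unknown.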

Other observations

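Region density followed gene density along the autosomes in 5 of the 6 lists. Over 22 autosomes, regions per Mb and protein-coding genes per Mb had Pearson's r of 0.905 with control shRNA, 0.922 with LACZ and 0.956 with SNAI2 in growth medium, and 0.906 and 0.953 after differentiation. The unadjusted p was 1e-05 in each, the smallest possible (permutation test, adjusted p = 1.2e-05, 12 relations in the family). Spearman's rho ran from 0.867 to 0.930, and without chromosomes 17 and 19, the farthest from the median gene density, r ran from 0.842 to 0.907. With SNAI2 shRNA r was 0.349 (permutation p = 0.0834) and rho 0.322 (p = 0.144), and chromosomes 16 and 10, with repeat-rich sequence next to their centromeres, had the highest region density. On arms alone it was 0.475 (permutation p = 0.0445, adjusted 0.0485), with rho 0.554 (adjusted p = 0.00874). Chromosomes are not independent replicates, and the difference between lists was not tested.

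A small core of 79 LACZ growth regions was found in all 6 lists, 76 of them on arms, including one in the epidermal differentiation band 1q21.3 (chromosome 1, 152729384 to 152729756). At the other end, 984 LACZ growth regions (12.6%) were also in the control list and in neither overexpression list, 784 of them on arms. Named regions of this kind, at 4q13.2 (chromosome 4, 68265135 to 68266816) and 9q21.11 (chromosome 9, 69710775 to 69711409), were also present with SNAI2 shRNA, as were 69 of the 984 (7.01%). With SNAI2 overexpression, regions private to both overexpression lists were about as wide as the rest, at medians of 295 and 306 bp.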
